A study of Homo sapiens with 6 samples.

How the data were processed

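PolyA RNA was measured by sequencing in 6 libraries of SiHa, an established human cervical squamous carcinoma line that carries papillomavirus sequence. Per the labels' protocols, cells were transfected with a vector plasmid or with a plasmid for the circular RNA hsa_circ_0005358 and were collected 72 h later, and each treatment has 3 libraries. The labels spell the name of the circular RNA in 3 ways that differ in their digits, and these were taken to mean the same RNA. The labels number the libraries but do not say that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. A circular RNA has no polyA tail and the table holds no circular transcripts, so the level of hsa_circ_0005358 itself was not analysed here.

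The authors deposited 1 table of FPKM values (fragments scaled by transcript length and library size) for 35544 loci, 2456 of which were at 0 in all libraries. Per the submitters' processing notes, Trimmomatic, HISAT2 and the genome build hg19 were used; their versions, the program that computed FPKM and its annotation are not given in the sources used here. Of the loci, 16797 carry identifiers of the kind made when transcripts are assembled from the reads, and some rows join several gene names. A row stood for a gene if it had a single name (34294 loci) or a single protein-coding name among several (381 loci). Another 805 loci with several names and 64 with none were tested and counted but not named. Where a symbol stood on several rows, the row with the highest mean kept it, which took the symbol from 161 loci. Of the transcript identifiers in the table, 97.3% were found in GENCODE 29, which supplied gene types, lengths and coordinates on GRCh38. The table itself holds no coordinates, so every position given is from GRCh38 and not from the build of the alignment.

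The table holds no read counts, and log-scale tests were therefore used. The value of 1 fragment on loci with 1 transcript of known length gave the depth relative to the deepest library: 98.1%, 100% and 99.4% for vector replicates 1 to 3, and 93.6%, 71.1% and 97.6% for circ_0005358 replicates 1 to 3. These depths are estimates, and no counting interval was drawn from them. Loci with FPKM of at least 1 in at least 3 of the 6 libraries were kept, and limma 3.58.1 in R 4.3.3 was run on log2(FPKM + 1) with a variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. For the genes in the study's title, an exact two-sided permutation test of the 3 against 3 values was added.

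Gene lists fixed before the data were examined, 41 in number, were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested. The test was repeated with an estimated correlation and with fry. List members were matched by symbol: 871 entries had a row of their own, 101 stood only in a row that joined several genes, and 33 had no row. The genes named are CDCP1, PTBP1, PTBP2 and PTBP3, then the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among those past the threshold with a symbol, a group mean of at least 1 FPKM and groups that did not overlap, and up to 4 members of each list with the smallest p. Pseudogenes and loci with the name of a sequenced clone were left out of the 12 and 12. Any other gene named was chosen after its values were seen, and is said to be.

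On simulated data with the spread of the real loci (10088 loci, 200 of them changed), the test of circ_0005358 against vector called 28% of 1.5-fold changes, 58% of 2-fold, 70% of 3-fold and 86% of 4-fold changes, with 12 unchanged loci called. A list shifted in the simulation was called and 0 of 32 unshifted lists were. The simulated loci varied independently, so false list calls that come from correlation between members could not appear there. In the real data the estimated correlation reached 0.286 for the simple and basal keratins. The alternatives were other pseudocounts (0.1 and 0.5), other filters, scalings, variance models and thresholds, library weights, a replicate block and each library left out. Rescaling to the same sum raised the libraries from FPKM sums between 138864 and 145278 to a larger common sum. The pseudocount of 1 then weighed less, so scaling and pseudocount changed together in that setting. Leaving a library out also removes loci expressed in 1 group alone, which then no longer reach the filter's 3 libraries. Leaving out vector replicate 3 and circ_0005358 replicate 2 together, and keeping only loci with 1 name, were chosen after the data were seen. Enrichment of the KEGG and GO terms listed in the deposited table used Fisher's exact test (scipy 1.17.1), one-sided, on terms with 10 to 300 tested loci, with tested loci that carry any term of that source as background. It was also chosen after the data were seen, as were medians of log2 fold change in windows of 50 neighbouring tested loci, which used the 9537 loci (92.6% of those tested) with a position, GC content and length, and 1000 shuffled orders. On simulated lists of loci, a planted term was called and 0 terms were called among randomly drawn loci. These loci were drawn independently, so false terms that come from correlation between members could not appear there either. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.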

Results

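Gene expression was compared between 3 SiHa libraries from cells given a vector plasmid and 3 from cells given a plasmid for hsa_circ_0005358, to look for mRNAs downstream of this circular RNA. The libraries listed between 23227 and 27803 loci above 0, with the highest number in vector replicate 3, and between 9976 and 10287 loci at FPKM of at least 1. The implied depth of circ_0005358 replicate 2 was 71.1% of that of the deepest library, and the other 5 libraries lay between 93.6% and 100%. Log2 values of the tested loci correlated at 0.932 to 0.939 within groups and at 0.908 to 0.917 between groups, and the first principal component, with 33.8% of the variance, separated the groups. On the second component, with 18.3% of the variance, replicate 3 of both groups lay at -21 and -22.7 and the other 4 libraries between 5.66 and 16.1.

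CDCP1, a transmembrane glycoprotein gene that the study followed as a downstream mRNA, was lower in all 3 libraries with the circular RNA plasmid than in any vector library. Its level fell from 19.95 ± 0.57 FPKM (SD, n = 3) with vector to 7.13 ± 0.34 FPKM (SD, n = 3), a ratio of 0.357. The libraries stood at 19.5, 19.8 and 20.6 FPKM with vector and at 7.32, 7.32 and 6.73 FPKM with circ_0005358. The log2 fold change was -1.37 with a standard error of 0.058 (limma, adjusted p = 0.000409). The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. CDCP1 (ENSG00000163814) lies on chromosome 3 from 45082278 to 45146422 on the minus strand of GRCh38.

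PTBP1, the gene of the RNA-binding protein named as the partner of the circular RNA, did not pass the test. It stood at 49.4, 45.2 and 46.4 FPKM with vector and at 38.5, 53.9 and 37.4 FPKM with circ_0005358, with a log2 fold change of -0.14 (standard error 0.15, limma adjusted p = 0.618, exact permutation p = 0.4). Its paralog PTBP3 had a log2 fold change of -0.11 (limma adjusted p = 0.843, exact permutation p = 0.9), with 26.3 FPKM in vector replicate 2 against 12.05 to 16.7 FPKM in the other 5 libraries. PTBP2 averaged 0.98 FPKM with vector and 0.773 FPKM with circ_0005358 and lay below the filter (exact permutation p = 0.2). PTBP1 (ENSG00000011304) lies on chromosome 19 from 797075 to 812327 on the plus strand of GRCh38.

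**Figure D1:**
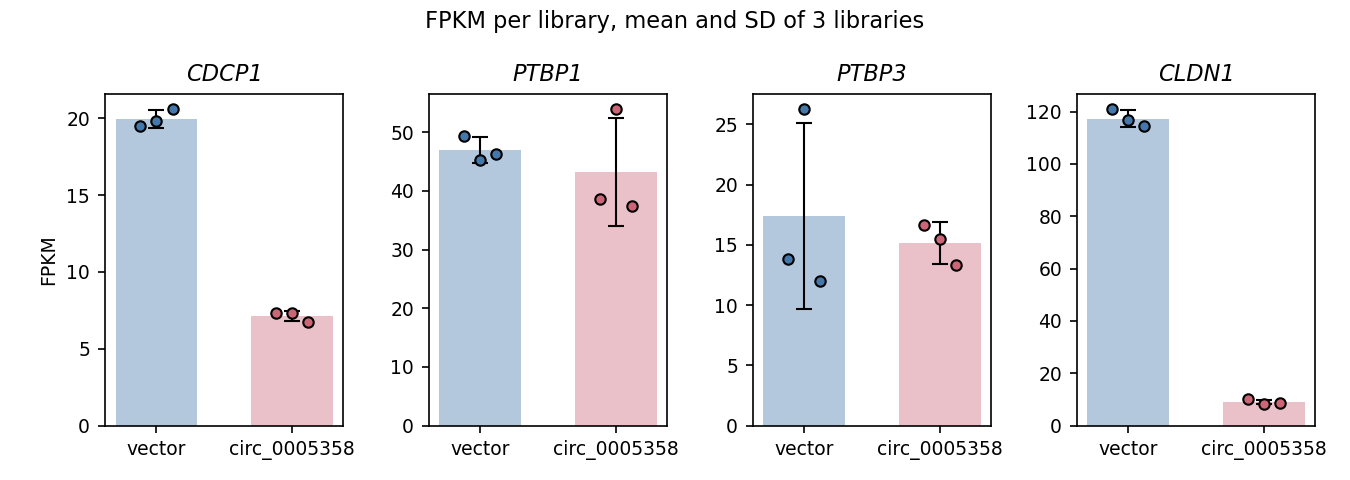
FPKM of CDCP1, PTBP1, PTBP3 and CLDN1 in each library (points), with the mean (bars) and SD (error bars) of 3 vector and 3 circ_0005358 libraries. CDCP1 averaged 19.95 FPKM with vector and 7.13 FPKM with circ_0005358, while the PTBP1 and PTBP3 libraries of both groups overlapped.

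Across the transcriptome, 1171 of 10295 tested loci changed, of which 660 were higher and 511 lower with circ_0005358. The share of changed loci that were higher was 56.4%, and it was 48.4% when each library was rescaled to the same sum, 48.7% without circ_0005358 replicate 3 and 47.5% without both vector replicate 3 and circ_0005358 replicate 2. It was 62.2% with FPKM of at least 5 in 3 libraries, so the more frequent direction depended on the setting. Of the changed loci, 173 changed at least 2-fold, 77 higher and 96 lower. Groups did not overlap in 35.8% of all tested loci, against 10% by chance. The count was 591 with no filter on low values, 528, 485 and 627 without vector replicates 1, 2 and 3, and 726, 761 and 563 without circ_0005358 replicates 1, 2 and 3, and it was 198 with vector replicate 3 and circ_0005358 replicate 2 both left out.

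The 12 named genes that fell most included CLDN1, CDH1 and CDH3, which encode cell adhesion proteins, and the keratin genes KRT16 and KRT80. CLDN1, a tight junction claudin, fell from 117 ± 3.31 to 9.10 ± 0.874 FPKM (SD, n = 3 each; log2 fold change -3.55, adjusted p = 5.54e-05). CDH1, which encodes E-cadherin, fell from 13.8 ± 4.37 to 0.958 ± 0.0821 FPKM, and CDH3, which encodes P-cadherin, fell from 10.3 ± 0.943 to 0.74 ± 0.0677 FPKM. The CDH1 call was lost when vector replicate 3 and circ_0005358 replicate 2 were both left out (adjusted p = 0.0642, the highest over its alternatives, with 0.00131 the lowest), as was the SOCS6 call (adjusted p = 0.0544, from 0.00139). Keratin genes KRT16 and KRT80 had log2 fold changes of -2.61 and -2.35, and LAMB3, a chain of the epithelial laminin whose row joins several names, fell from 38.6 to 7.36 FPKM. NPNT, an integrin ligand of basement membranes, fell from 17.1 to 1.27 FPKM, and CRTAC1, a secreted cartilage protein gene, from 16.0 to 0.741 FPKM. XYLT1, which starts proteoglycan sugar chains, fell from 5.25 to 0.214 FPKM, and CA2, a carbonic anhydrase gene, from 6.11 to 0.503 FPKM. SOCS6, a suppressor of cytokine signalling, had a log2 fold change of -2.55. ZMAT3, a p53 target, had a log2 fold change of -2.19 (adjusted p = 0.0327), and its 3 libraries with circ_0005358 stood at 2.31, 8.01 and 2.14 FPKM. The ZMAT3 call was lost with no filter on low values (adjusted p = 0.0855), without vector replicates 1, 2 or 3 (adjusted p = 0.107, 0.0976 and 0.0981) and without circ_0005358 replicates 1 or 3 (adjusted p = 0.0912 and 0.0925), but not without circ_0005358 replicate 2 (adjusted p = 0.00267, the lowest over its alternatives).

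The genes that rose most included 4 loci that were near or at 0 in every vector library. CEBPD, a transcription factor of the acute phase, was at 0.0316, 0.00466 and 0.0213 FPKM with vector and at 37.0, 28.8 and 26.1 FPKM with circ_0005358. HNRNPA0, an RNA-binding protein gene of ubiquitous expression, was listed at 0 in all 3 vector libraries and at 19.05, 19.2 and 18.4 FPKM with circ_0005358. For CEBPD and HNRNPA0, which have no intron, FPKM alone does not show whether the values at or near 0 came from the cells or from how fragments were assigned to loci. GLI1, the transcription factor at the end of hedgehog signalling, stood at 0.03, 0.0241 and 0.398 FPKM against 14.4, 15.3 and 14.98 FPKM. PAPPA, a protease of insulin-like growth factor binding proteins, rose from 0.346 to 5.19 FPKM. A2M, a broad protease inhibitor, rose from 7.57 to 57.2 FPKM (log2 fold change 2.77, adjusted p = 0.000437), SAA1, an acute-phase protein gene, from 10.8 to 53.3 FPKM, and EFEMP1, an extracellular matrix gene, from 10.03 to 53.3 FPKM. CPS1, the first enzyme of the urea cycle, rose from 12.5 to 64.8 FPKM. The imprinted noncoding H19 rose from 0.437 to 7.91 FPKM, and TRIM14, an antiviral signalling gene, from 1.86 to 14.8 FPKM. TINCR rose from 0.512 to 5.48 FPKM, a call lost at a pseudocount of 0.1 (adjusted p = 0.0541, the highest over its alternatives, with 0.00317 the lowest). SFT2D2 had a log2 fold change of 2.29 (adjusted p = 0.0186), and its call was lost without vector replicates 1 or 2 (adjusted p = 0.0549 and 0.0715) and without circ_0005358 replicates 1, 2 or 3 (adjusted p = 0.0665, 0.0617 and 0.0657), but not without vector replicate 3 (adjusted p = 0.00399, the lowest over its alternatives).

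**Figure D2:**
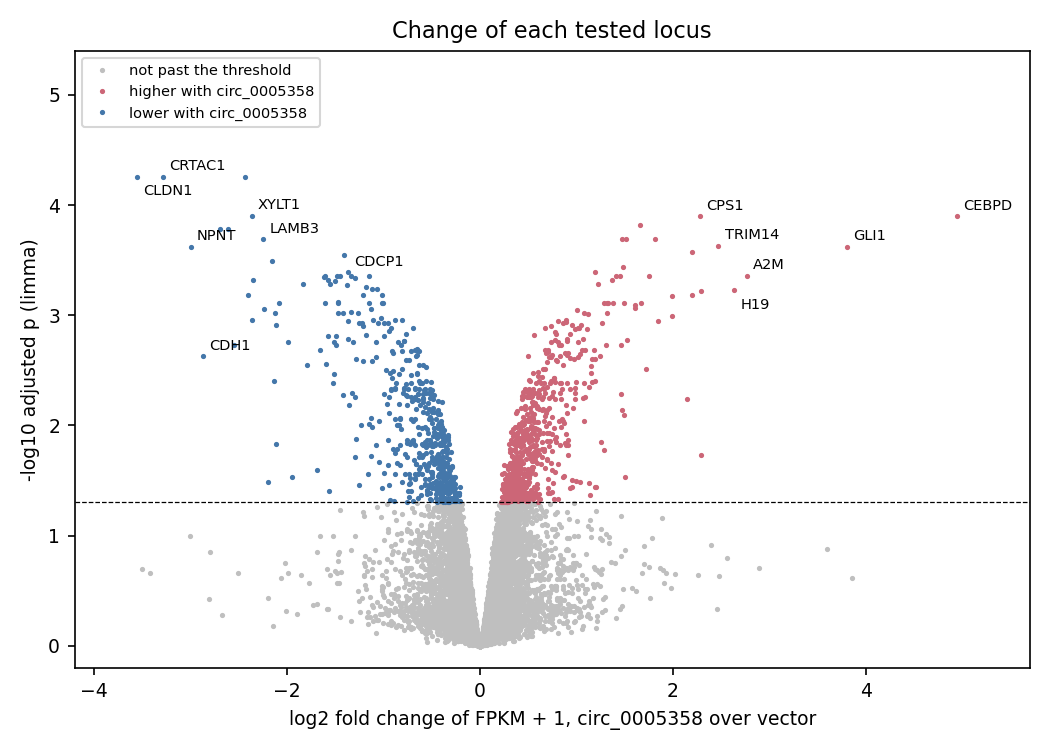
Log2 fold change of FPKM + 1 (x axis) against the -log10 adjusted p of limma (y axis) for the tested loci, with the dashed line at the threshold. HNRNPA0, at 0 in every vector library, is not drawn. Of the 10295 loci tested, 660 were higher and 511 lower with circ_0005358.

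Of 34 gene lists with enough tested members, 10 passed camera's threshold, 3 higher and 7 lower. With an estimated correlation camera called 0 lists, with 5 at an unadjusted p under 0.05 and a smallest adjusted p of 0.161. The estimate exceeded the preset correlation of 0.01 for the epithelial junction, keratin, TGF-beta and p53 lists (0.0815 to 0.286). For the other called lists it lay below, between -0.0736 and 0.00745. The unadjusted camera p of these other lists still rose, for NRF2 targets from 2.08e-07 to 0.0049. A correlation above the preset one therefore does not account for their lost calls. With an estimated correlation camera also takes its degrees of freedom from the few libraries, and with a preset one from the many loci. The adjusted p with an estimated correlation thus reflects this change as well as the correlation, and their shares were not tested. By fry, 19 lists moved on balance in 1 direction.

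Epithelial junction and identity genes fell together: 12 of 15 tested members fell and 0 rose, with a median log2 fold change of -0.64 (camera adjusted p = 3.03e-09; adjusted p = 0.161 with an estimated correlation). Adjusted over the list alone, 13 fell and 1 rose. CLDN1 and CDH1 led the list, DSP, which encodes desmoplakin, fell from 18.6 to 5.88 FPKM, and ST14, the matriptase gene, from 1.84 to 0.224 FPKM. Among simple and basal keratins, 5 of 6 fell, and 5 also when adjusted over the list alone (camera adjusted p = 3.24e-05; adjusted p = 0.266 with an estimated correlation). KRT8 fell from 180 to 85.1 FPKM, KRT18 from 142 to 94.9 FPKM and KRT7 from 348 to 269 FPKM.

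Targets of NRF2, the regulator of oxidative stress defence, rose: 12 of 22 rose and 0 fell, and 14 rose when adjusted over the list alone (camera adjusted p = 3.53e-06; adjusted p = 0.161 with an estimated correlation). The aldo-keto reductases AKR1C1 and AKR1C3 rose from 1.56 to 9.17 FPKM and from 16.8 to 50.5 FPKM, PIR from 5.68 to 10.2 FPKM, and TKT, an enzyme of the pentose phosphate pathway, from 39.2 to 57.3 FPKM. AKR1C1 and AKR1C3 lie in a stretch of chromosome 10 whose 50 tested loci had a median log2 fold change of 0.21. Of 29 S phase and replication genes, 8 rose and 1 fell (9 and 1 when adjusted over the list alone; camera adjusted p = 0.0451; adjusted p = 0.266 with an estimated correlation). The helicase subunits MCM6, MCM7 and MCM4 rose from 34.6 to 61.8, from 48.5 to 69.1 and from 61.7 to 95.1 FPKM, and they lie in windows of 50 tested loci with medians of 0.34, 0.15 and 0.12. Of 40 nuclear genes of oxidative phosphorylation, 4 rose and 0 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.0451, and 0.266 with an estimated correlation). Among them was COX5A, from 32.7 to 42.4 FPKM, in a window with a median of 0.18. For list members in windows, the median was also taken after subtracting each member's window median. It went from 0.481 to 0.37 for NRF2 targets, from 0.086 to 0.087 for S phase and from 0.124 to 0.116 for oxidative phosphorylation.

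Of 14 NF-kB targets and cytokines, 4 fell and 0 rose (7 fell when adjusted over the list alone; camera adjusted p = 0.00612; adjusted p = 0.259 with an estimated correlation): BIRC3, IL6, LIF and CXCL1, with IL6 at 4.98 and 1.41 FPKM. Of 9 genes that sense DNA or RNA, DDX58 alone fell, from 7.73 to 4.63 FPKM, the only call also when adjusted over the list alone (camera adjusted p = 0.047; adjusted p = 0.266 with an estimated correlation). Among 19 TGF-beta targets, 7 fell and 2 rose (8 and 2 when adjusted over the list alone; camera adjusted p = 0.00732; adjusted p = 0.43 with an estimated correlation). TGFBI, PMEPA1 and BHLHE40 fell, with PMEPA1 at 9.80 and 2.90 FPKM, while CTGF and TGFB1, chosen after their values were seen, rose. Of 24 p53 targets, 4 fell and 0 rose (6 fell when adjusted over the list alone; camera adjusted p = 0.0451; adjusted p = 0.484 with an estimated correlation): MDM2, PMAIP1, TP53INP1 and ZMAT3. Of 15 metastasis suppressors and promoters, 2 fell and 1 rose (7 and 1 when adjusted over the list alone; camera adjusted p = 0.0451; adjusted p = 0.266 with an estimated correlation). These were MSN and PODXL, a cytoskeletal linker and a sialomucin gene, which fell, and ANXA2, which rose. With FPKM of at least 5 in 3 libraries the NF-kB call was lost, with a median log2 fold change of -0.03 in place of -0.33 (camera adjusted p = 0.872, the highest over its alternatives, with 0.00126 the lowest). That filter also ended the metastasis, S phase, oxidative phosphorylation and sensing calls (adjusted p = 0.258, 0.114, 0.177 and 0.413), and so did quantile normalization (adjusted p = 0.053, 0.0577, 0.0751 and 0.053). With no filter the metastasis and p53 calls were lost (adjusted p = 0.0616 and 0.0748), and after rescaling to the same sum the oxidative phosphorylation call was (adjusted p = 0.0532). The TGF-beta call was lost without vector replicate 2 (adjusted p = 0.0595), the metastasis call without circ_0005358 replicates 1 or 3 (0.142 and 0.0588), and the p53 call without vector replicates 2 or 3 or circ_0005358 replicate 1 (0.0674, 0.112 and 0.0688). The oxidative phosphorylation call was lost without vector replicates 2 or 3 or circ_0005358 replicate 1 (0.141, 0.112 and 0.0637), and the S phase call without vector replicates 1, 2 or 3 or circ_0005358 replicate 3 (0.0503, 0.0779, 0.112 and 0.0736). The sensing call was lost without vector replicates 2 or 3 (0.0674 and 0.0863) and without circ_0005358 replicates 1, 2 or 3 (0.0519, 0.0793 and 0.096).

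**Figure D3:**
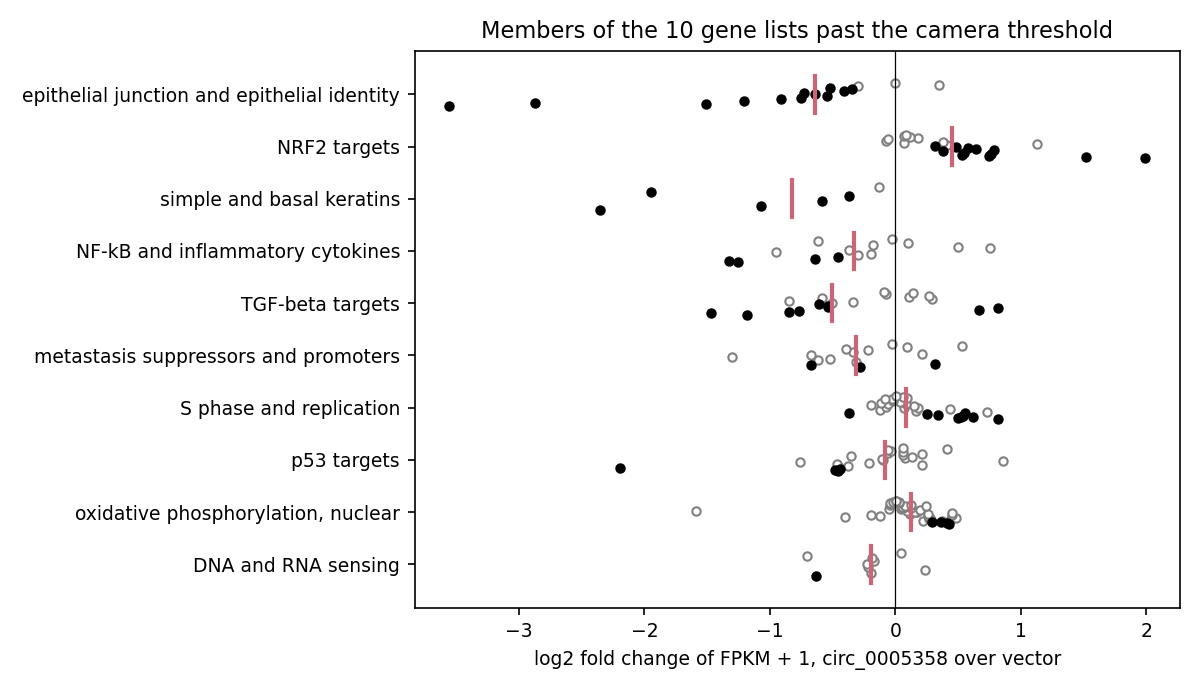
Log2 fold change of FPKM + 1 for each tested member (points) of the 10 gene lists past camera's threshold. Filled points passed limma's threshold and vertical bars mark list medians. In the epithelial junction list, 12 of 15 members fell.

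The other 24 tested lists did not pass, with camera adjusted p from 0.112 to 0.982. Mesenchymal genes moved both ways: 5 of 21 rose and 7 fell (6 and 10 when adjusted over the list alone; adjusted p = 0.262), with THBS1 rising from 14.95 to 49.4 FPKM and TGFBI falling from 12.9 to 5.11 FPKM. Laminins and basement membrane genes also split, with 2 of 10 rising and 3 falling (5 and 3 when adjusted over the list alone; adjusted p = 0.937). Their median was 0.25 and camera pointed up, while their mean was -0.19 and fry pointed down. LAMB3 and LAMA3 were among those that fell, and LAMB1 was among those that rose. Among 16 matrix proteases and inhibitors, 3 rose and 4 fell (3 and 8 when adjusted over the list alone; adjusted p = 0.112): ADAMTS1 rose from 6.40 to 14.97 FPKM and MMP14 fell from 37.7 to 28.7 FPKM. Of 16 genes of SRC family and CDCP1-linked signalling, CDCP1 and ST14 fell and LYN and PRKCD rose (3 rose and 2 fell when adjusted over the list alone; adjusted p = 0.982). Of 25 interferon response genes, 1 rose and 5 fell (4 and 9 when adjusted over the list alone; adjusted p = 0.125), with ISG15 falling from 16.5 to 9.80 FPKM and IFI44L rising from 0.319 to 1.44 FPKM. Of 31 mitotic genes, FOXM1 alone rose, also when adjusted over the list alone (adjusted p = 0.982). Of 32 spliceosome and hnRNP genes, SRSF5 rose and MBNL2 fell, the same counts as adjusted over the list alone (adjusted p = 0.506). Median, mean, camera and fry also differed in sign for the SRC, mitotic, WNT, apoptosis, autophagy, heat shock, cholesterol, housekeeping, NOTCH and antigen presentation lists, none of which camera called.

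Lists with fewer than 5 tested members were not tested. Squamous differentiation had 4 tested members, the most abundant being KRT17 with a highest group mean of 625 FPKM. The most abundant leukocyte and fibroblast markers were CD14 and LUM, with highest group means of 11.4 and 7.47 FPKM. The most abundant endothelial, erythroid and neural markers, PECAM1, HBA1 and SNAP25, reached 0.301, 0.198 and 0.146 FPKM. In the list of mitochondrially encoded genes only MT-RNR1 had a row of its own, and it reached 5.69 FPKM.

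Fold changes were not spread evenly along the genome. Over 180 windows of 50 neighbouring tested loci, the window medians had an SD of 0.102, against 0.0507 for the highest of 1000 shuffled orders. On chromosome 2, 3 windows with starts from 87454781 to 164573741 had medians of 0.20, 0.18 and 0.34, and the 2 windows from 201233443 to 233475520 had medians of -0.13 and -0.17. On chromosome 7 the 2 windows from 192969 to 34928876 had medians of -0.11 and -0.19, and the last window, from 140023744 to 152463786, had a median of 0.31. The 5 windows of chromosome 9 from 88388419 to 137062124 had medians between 0.19 and 0.29, and the first window of that chromosome had a median of -0.11. Both windows of chromosome 21 had medians of 0.21. The 24 windows with a median above 0.15, 13.3% of all windows and picked on the same values, held 239 of the 600 higher loci that lay in windows (39.8%) and 26 of the 444 lower loci (5.9%). PAPPA and TRIM14, on chromosome 9, lie in windows with medians of 0.27 and 0.24, while CDCP1 lies in a window with a median of -0.01.

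**Figure D4:**
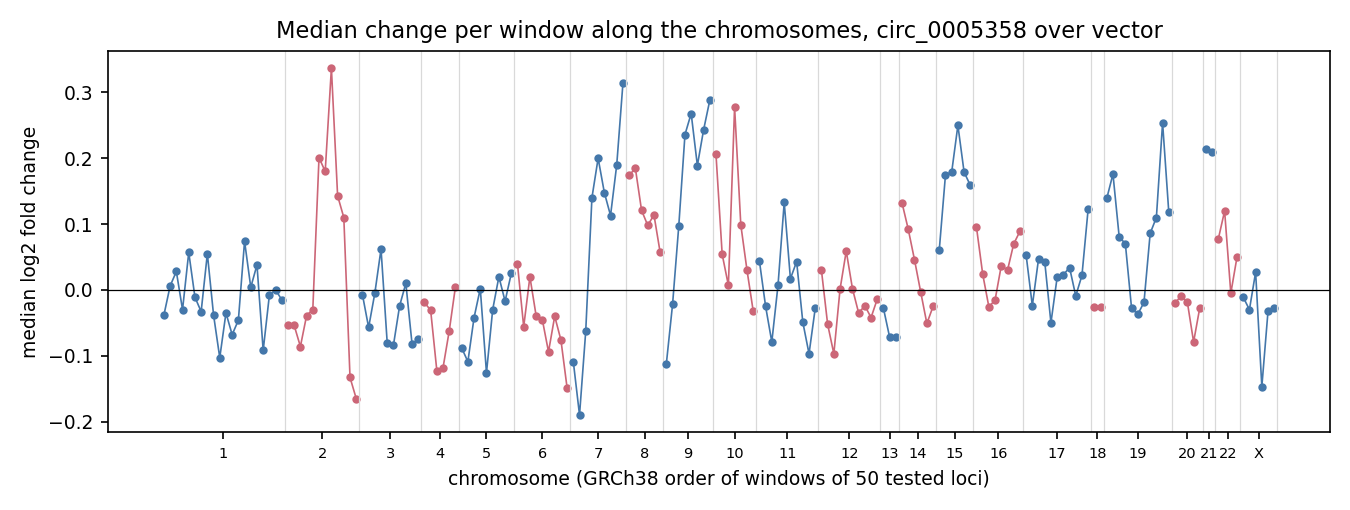
Median log2 fold change (y axis) in 180 windows of 50 neighbouring tested loci, in their order along the chromosomes of GRCh38 (x axis, colours alternate by chromosome). Window medians lay between -0.19 and 0.34.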

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

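All alternatives were chosen before the data were examined, except leaving out vector replicate 3 and circ_0005358 replicate 2 together and keeping only loci with 1 name. CDCP1 kept its direction and its side of the threshold under every alternative run (adjusted p from 0.000315 to 0.0298), and PTBP1 stayed short of the threshold under every one. The count of 1171 changed loci fell to 591 with no filter on low values, where many more loci are adjusted for. It was 473 at a fold change of at least 1.5, 173 at 2, 1871 at an adjusted p under 0.1 and 2813 at an unadjusted p under 0.05. It was 198 with both doubtful libraries left out, and between 485 and 761 with any 1 library left out, where fewer samples enter the fit. The count of called lists, 10 of the 34 tested, was 5 with FPKM of at least 5 and 6 after quantile normalization. It was 6 with both doubtful libraries left out and 5 to 11 with 1 library left out. By fry it was 19, and with an estimated correlation 0. Apart from the fewer samples, and the fewer degrees of freedom with an estimated correlation, the cause was not tested. Of the 24 largest changes, 12 passed with both doubtful libraries left out, and 16 to 19 with 1 library left out. CDH1 and SOCS6 lost their calls with both left out, SFT2D2 and ZMAT3 with single ones and ZMAT3 also with no filter, and the others that did not pass with libraries left out were not tested there, because fewer than 3 libraries reached the filter. CDCP1, the 24 largest changes and the called lists kept their sign wherever they were tested. Signs of the other called loci were not followed. PTBP3, which was not called, went from -0.11 to 0.21 without vector replicate 2. Single genes kept their side of the threshold in 417 comparisons and lost it in 16, and lists in 164 and 46.

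With the replicate number as a block, 259 loci changed, 129 higher and 130 lower. The adjusted p was then 0.086 for SFT2D2, 0.105 for ZMAT3, 0.0826 for the S phase list and 0.0962 for the sensing list. The labels do not pair the libraries, and same-numbered libraries deviated together with correlations of 0.064, 0.048 and 0.078. Each library correlated best with its own number, and replicate 3 of both groups lay apart from the rest on the second principal component (-21 and -22.7), so a structure shared by number stays open. Tests on read counts were planned only in case counts were found and were not run. Depth limits low loci most, since 1 fragment on a kilobase is worth more FPKM in circ_0005358 replicate 2, the shallowest library.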

Other observations

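The enrichment of terms, the windows along chromosomes, the loci near 0, the single-library swings, the comparison of lincRNA with coding loci and the scaling check on epithelial genes were chosen after results had been seen. Genes named in the next 2 paragraphs were chosen after their values were seen, from the enriched terms.

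Growth factor genes were over-represented among the loci that fell: 13 of 36 tested genes of the GO term growth factor activity fell, where 1.83 would be drawn by chance (adjusted p = 7.89e-06). They included AREG, BTC, EPGN, EREG and TGFA, ligands of the epidermal growth factor receptor, and VEGFA and VEGFC, growth factors of vessels. Actin binding genes fell in 35 of 194 cases against 9.89 by chance (adjusted p = 8.51e-08), among them the myosins MYO10, MYO5C and MYO6. Genes of the KEGG pathway ECM-receptor interaction fell in 8 of 33 cases against 1.83 by chance (adjusted p = 0.0298), among them the integrins ITGA6 and ITGB4 and the syndecan SDC4.

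Matrix genes moved both ways: 20 of 83 tested genes of the GO term proteinaceous extracellular matrix rose, against 5.67 by chance (adjusted p = 0.000252), including COL6A1, COL12A1, FBLN1, CCDC80 and SPOCK1, and 11 fell, against 4.23 (adjusted p = 0.135). Of 77 genes of extracellular matrix organization, 14 fell against 3.92 by chance (adjusted p = 0.00618) and 11 rose against 5.26 (adjusted p = 0.354). Serine protease inhibitors rose in 10 of 26 cases against 1.78 by chance (adjusted p = 0.00131), among them SLPI, PI3, SERPINE2 and A2M, and fell in 6 against 1.32 (adjusted p = 0.0889), among them SERPINB5 and SPINT1. Xenobiotic metabolism by cytochrome P450, a KEGG pathway, rose in 9 of 19 cases against 1.67 by chance (adjusted p = 0.00215), with CYP1A1, ALDH3A1, GSTP1 and MGST2 among them.

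Fold changes shifted together along chromosomes. A correction for GC content and length left the SD of window medians at 0.098, with 98.0% of its excess over shuffled orders kept, which argues against such a bias as the whole cause. The highest SD among the 9 other splits of the libraries was 0.0596, and single-library differences stay open, since that split exceeded its shuffled orders by 0.03, against 0.0584 for the real split, and the other splits hold part of the real contrast. Medians of neighbouring windows correlated at 0.69, against at most 0.18 in 100 shuffled orders, above the bound set beforehand for a gain or loss of chromosome regions between the 2 cell populations. The vector and circ_0005358 cells may therefore have differed in chromosome content, and neighbouring genes regulated together were not tested.

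Epithelial junction genes fell together. Under the 3 other scalings the list's median stayed at -0.63 or beyond, which argues against library scaling. The median change of the 20 nearest loci around the genes that fell was 0.04, from -0.077 around EPCAM to 0.226 around SPINT1. This argues against wide chromosome regions around these genes lost in the circ_0005358 cells. It cannot show a loss confined to a few neighbouring genes. CDH3 and CDH1, which start at 68636189 and 68737225 on chromosome 16, both fell, to ratios of 0.072 and 0.069. Here, as for CDCP1 and every other locus, an effect of the circular RNA cannot be told apart from another difference between the cells of the 2 treatments. Any such difference would coincide with the treatment, and 0 label fields name a culture, clone, batch or passage.

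Vector replicate 3 listed more loci above 0 than the other 5 libraries, at 99.4% of the depth of the deepest. Its median over protein-coding loci silent elsewhere, olfactory receptors apart, was 0.103 FPKM, against 0.0053 to 0.0071 FPKM in the other 5 libraries. Silence was set for each library by the mean of the other 5, so the loci compared differ. They numbered 5265 for vector replicate 3 and 3719 to 3773 for the others, whose sets leave out loci that vector replicate 3 raised. For RNA of another cell type, no marker list (leukocyte, fibroblast, endothelial, erythroid or neural) exceeded 1.26 times the median of silent coding loci, short of the bound set beforehand. The lists held only 1 to 4 silent members, with medians between 0.0316 and 0.1245 FPKM. Their most abundant genes, CD14 and LUM, stood at 10.5 and 9.21 FPKM there. So few members near the floor cannot decide for or against another cell type. For genomic DNA, the test set beforehand was open (olfactory receptor genes at 0.31 times the median of other silent loci), but lincRNA loci rose by only 0.16 times as much as coding loci, which argues against DNA spread evenly over the genome. DNA enriched for coding exons was proposed next and also argued against by its test. That was a Spearman rho of 0.08 across loci between FPKM and the coding share of the transcript. The source stays open, and no explanation from the SiHa cells themselves was tested.

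Of the 10 splits of the 6 libraries, 1, the real one, gave as many changed loci, 1171 against at most 18 in the others, and 1, the real one, gave as many changed lists, 10 against at most 3. These splits are too few for a share under 0.05. The other splits also hold part of the real contrast within their groups, which lowers their counts. Their counts therefore do not show what libraries without a contrast would give.

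Loci below 0.5 FPKM in every library of 1 group and above 5 FPKM in every library of the other numbered 4, all of them near 0 with vector. Of these, 2 (CEBPD and HNRNPA0) have no intron, against 74 of 5726 loci with a mean of at least 5 FPKM. Of 3300 loci with a mean of at least 10 FPKM, 153 had 1 library more than 2-fold from all 5 others, and the share was 16.2% for loci with 1 transcript and 2.7% for loci with over 5.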
